A study of Mus musculus with 9 samples.

How the data were processed

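Labelled RNA from 9 samples in 3 groups of 3 (induced cells, islets and non-islet pancreatic cells of the mouse) had been hybridized to Illumina bead arrays with 24613 probes. Per the labels RNA was extracted with Trizol, amplified with the Ambion TotalPrep kit and labelled with biotin. The deposited intensity values were made by the authors with BeadStudio, which the submitters' processing notes name without version or settings. From the values, these intensities were on a linear scale, background had been subtracted, since 25.4%, 25.8% and 33.8% of values in the induced, islet and non-islet groups were below 0, and every array had the same mean. They had not been quantile-normalized. A further deposited table with detection p-values has 36 columns named by slide position only, which no label ties to a sample, and was not used here. Its positions lie on 2 slides with 3 and 6 arrays, and which group lay on which slide is not given, so that a slide effect cannot be told apart from the groups.

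Values were quantile-normalized, an offset of 11.9 was added, the smallest that brings the lowest value to 1, and log2 was taken. The design fixed before the files were opened assumed detection p-values for the filter. As these could not be used, the noise SD of each array was estimated from the values below 0 mirrored at 0, and a probe counted as above background beyond 1.645 noise SD. Probes above background on all 3 arrays of at least 1 group were kept, 13928 in all. Of the probes, 20984 carried 1 gene symbol, 1 carried several and 3628 none; 20968 were found by gene number in the reference gene table (GRCm38) and 0 symbols changed. The kept probes comprised 12217 with a symbol, for 9937 genes, and 1711 without; 1826 genes had several kept probes, and the brightest by mean log2 stood for the gene. A gene that was above background on no array of 1 group and on all of the other is given as at least so many fold, against the background limit. This bound is that of the gene's brightest probe, and other probes of the gene can lie below it.

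Groups were compared with limma 3.58.1 (lmFit and eBayes, 1 mean per group over all 9 arrays, 6 residual degrees of freedom) in R 4.3.3, and every adjusted p for a gene or probe comes from limma's moderated test, two-sided, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. All 3 pairs of groups were compared. The 25 gene lists were fixed before the data were seen: beta cell, other islet hormone cells, pan-endocrine secretory granule, endocrine transcription factors, acinar cell, acinar transcription factors, duct cell, stellate and fibroblast, endothelial, macrophage and myeloid, class II antigen presentation, T and B lymphocyte, NK and cytotoxic, interferon response, class I antigen processing, pancreatic injury and regeneration, endoplasmic reticulum stress, immediate early and dissociation stress, proliferation, genes usually low in beta cells, respiratory chain, ribosomal proteins, adipocyte, Schwann and neural, and erythrocyte. Lists with at least 5 measured genes were tested with camera (limma) at a preset correlation of 0.01, with adjustment over the lists of a comparison, then with an estimated correlation and with fry. A list's calls that do not carry a p with an estimated correlation in the text held under it.

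Named genes followed a rule fixed beforehand: a panel of 30 pancreatic genes, of which 25 had a kept probe, the 5 largest rises and 5 largest falls among called genes whose 3 arrays in each group did not overlap (which chance gives in 10 percent of genes for 3 against 3), and up to 4 called members of each list with the largest changes. Islet-enriched and non-islet-enriched genes differed by at least 4-fold between islets and non-islet cells with a call. Position is the induced minus non-islet difference over the islet minus non-islet difference.

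Alternatives were offsets of 16 and 50, scaling to a common median, the deposited values without quantile normalization, scaling by the noise SD (chosen after seeing the data), no filter, a stricter filter, probes above background on all arrays, a trended variance, array weights, 1 probe per gene, at least 2-fold, the 2 compared groups alone, a replicate block, other probes of a gene, other fold limits and sets, the linear scale, Spearman correlation, and leaving out each array in turn. The series value table was the source used throughout, so it gave no further alternative.

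The procedure was tested on simulated data for the comparison of induced cells with islets, with 200 changed probes in each of 10 simulations. At log2 changes of 0.5, 1 and 2 it recovered 42.7%, 88.2% and 99.4% of them, and 4.6% of calls were false. In the data 6775 probes were called in this comparison, so these rates apply to far fewer changes than were found. Rates for the comparisons with non-islet cells were not summarized and are not given here. The median replicate SD of log2 signals was 0.191 in non-islet cells, 0.0838 in induced cells and 0.0907 in islets. The simulated arrays instead had a common spread per probe in all groups, so the rates do not cover this unequal spread. Planted list shifts were called in 10 of 10 simulations and unchanged lists in 0, and a planted position of 0.6 was returned as 0.597 to 0.603. Python 3.11.15 with matplotlib 3.10.9 drew the figures.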

Results

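Gene expression was measured on Illumina mouse bead arrays in 3 groups of samples from the adult mouse pancreas, with 3 arrays per group. The induced cells carried green fluorescent protein (GFP) and were sorted by flow cytometry from the pancreas of Rag-deficient mice. These mice lack mature T and B lymphocytes. The sort took place 1 month after an adenovirus named M3 had been given. By the labels 22% of the sorted cells were insulin-positive, and each sample held 5000 cells or so. M3 is not spelled out in the labels. In the published work on this system it stands for a set of transcription factor genes that includes Pdx1 and Neurog3. The islet samples were 4 to 5 islets picked by hand from mice with a Pdx-GFP transgene, and so contained beta cells together with the other hormone cells and the vessels of the islet. The non-islet samples were pancreatic cells left after islets had been taken out of Pdx-GFP mice, some 10000 cells each, a tissue made up mostly of enzyme-secreting acinar cells. The induced samples thus came from another mouse line than both other groups, and the Y-linked genes Eif2s3y and Kdm5d, chosen after their values were seen, were above background on 3 of 3 induced arrays and on 0 of 3 in each other group, while Uty and Usp9y, also Y-linked, were above background on no array. Silent on every array, the probes of Uty and Usp9y say nothing on sex. Eif2s3y and Kdm5d averaged 182.2 and 30.94 in the deposited values of induced cells and were negative in both other groups. They argue for male cells in the induced samples alone. Line and sex cannot be told apart from the group in either comparison of induced cells. The arrays of a group are called independent repeats and nothing says that they came from separate animals, so the p-values measure the spread between these samples, which may be technical.

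The deposited values had a mean of 74.2 on every array. On average 13592 ± 108 probes of 24613 were above background on the induced arrays (SD, n = 3), 13679 ± 132 on the islet arrays and 9544 ± 365 on the non-islet arrays. The 50 brightest probes held 13.3%, 15.5% and 44.9% of the signal in the induced, islet and non-islet groups, and the noise SD averaged 1.52, 1.94 and 4.55. In these groups 17.3, 15.3 and 18.3 probes per array lay within 20% of the highest value, and whether folds are compressed there was not tested. The number of arrays limits the precision. Correlations of log2 signals between arrays averaged 0.995 within the induced group, 0.995 within the islet group and 0.978 within the non-islet group. Between groups the mean correlation was 0.886 ± 0.000759 for induced with islet arrays, 0.737 ± 0.00591 for induced with non-islet arrays and 0.742 ± 0.0082 for islet with non-islet arrays (SD over 9 array pairs). These correlations are across probes, which are not independent replicates. The first principal component carried 70.5% of the variance and set the non-islet arrays apart from both other groups, and the second carried 24.4% and separated induced from islet arrays.

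Induced cells were first compared with islets, the comparison named in the title of the series. The sorted induced cells held several islet hormone transcripts at high level, but their signal fell short of islets for most genes of the beta cell list. By the labels 22% of these cells were insulin-positive. A lower signal can thus mean fewer expressing cells or less transcript per cell, which the arrays cannot tell apart. Signal of Ins2, an insulin gene, was 7162 ± 1961 in induced cells and 11180 ± 1028 in islets (SD, n = 3), a log2 difference of -0.68 (SE 0.22). Gene signals are quantile-normalized, and the brightest exceed the highest deposited value on the induced and islet arrays (6509.4 and 8363.5). Iapp, which encodes the peptide secreted with insulin, had a signal of 1520 ± 174 against 6616 ± 511 in islets. Ucn3, a peptide of mature beta cells, was above background on 1 of 3 induced arrays and had a signal of 806 ± 28.1 in islets. Genes of injured epithelium, of the interferon response and of class I antigen presentation were higher in induced cells, and genes of the endothelium were lower.

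Of 23 measured genes in the beta cell list, 4 were higher and 15 lower in induced cells (5 and 15 adjusted over the list alone; median log2 difference -0.73, camera adjusted p = 0.000817). The lower genes included Slc30a8, which loads zinc into insulin granules (-2.97, SE 0.10), G6pc2, a glucose-6-phosphatase of the islet (-2.36), Slc2a2, the glucose transporter of mouse beta cells (-2.09), Cltrn, which encodes the membrane protein collectrin (-3.90), and Iapp (-2.12, adjusted p = 4.38e-07). Ucn3, above background on 1 of 3 induced arrays, stood at -5.95, a size that depends on the offset. Nkx6-1, a beta cell transcription factor, was lower as well (-0.73, adjusted p = 0.00215). Npy, a neuropeptide gene, was higher (3.45, SE 0.12), and so were Pdx1 and Pcsk1, a prohormone convertase gene whose probe was dim in every group (0.63, adjusted p = 0.000684). Pdx1 had a signal of 2003 ± 80.0 in induced cells and 250 ± 13.4 in islets (log2 difference 2.95, adjusted p = 1.52e-08). Whether its probe also reads the viral transcript is not known.

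Among the other hormone genes, Ppy fell from a signal of 11640 ± 192 in islets to 221 ± 8.82 in induced cells (adjusted p = 6.48e-10), Gcg, the glucagon gene, was lower at a log2 difference of -2.27 (SE 0.13) and Sst, the somatostatin gene, at -0.93 (adjusted p = 1.46e-05). Pyy had a signal of 11370 ± 564 in induced cells and 10440 ± 665 in islets, a difference within the spread of the replicates (adjusted p = 0.366). The list of other islet hormone cells had 3 of 12 genes higher and 6 lower, both also adjusted over the list alone, and was not called (camera adjusted p = 0.202). Peg3, an imprinted gene, was lower (-2.47), and Etv1, a transcription factor gene, was higher by its brightest probe but not by its other kept probes (0.10 and 0.19, adjusted p = 0.609 and 0.185). Of 27 genes for the secretory granule common to endocrine cells, 3 were higher and 18 lower, with the same counts adjusted over the list alone (median -0.60, camera adjusted p = 0.000723). Syt4, a synaptotagmin gene, Scg2, a granin gene, and Pcsk1n, which encodes an inhibitor of prohormone convertase, were lower at -3.95, -3.39 and -3.11. Chgb, another granin gene, and Stx1a, a syntaxin gene of the exocytosis machinery, were higher by 2.35 and 2.38, and Chga was not called (-0.29, adjusted p = 0.341).

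The list of endocrine transcription factors had 4 of 16 genes higher and 6 lower, also when adjusted over the list alone, and was not called (median -0.18, camera adjusted p = 0.408). Besides Pdx1, Neurod1 was higher (0.62, SE 0.20, adjusted p = 0.0246), as was Foxa1 by at least 1.56-fold (adjusted p = 1.5e-05). Isl1, a factor of all islet hormone cells, was lower (-2.88, adjusted p = 3.29e-09), as was Nkx2-2 (-0.54, adjusted p = 0.00493). Neurog3, which starts endocrine development, was not above background on any induced array and was at least 2.42-fold lower than in islets (adjusted p = 1.33e-05). Whether its probe reads the viral transcript is not known.

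**Figure D1:**
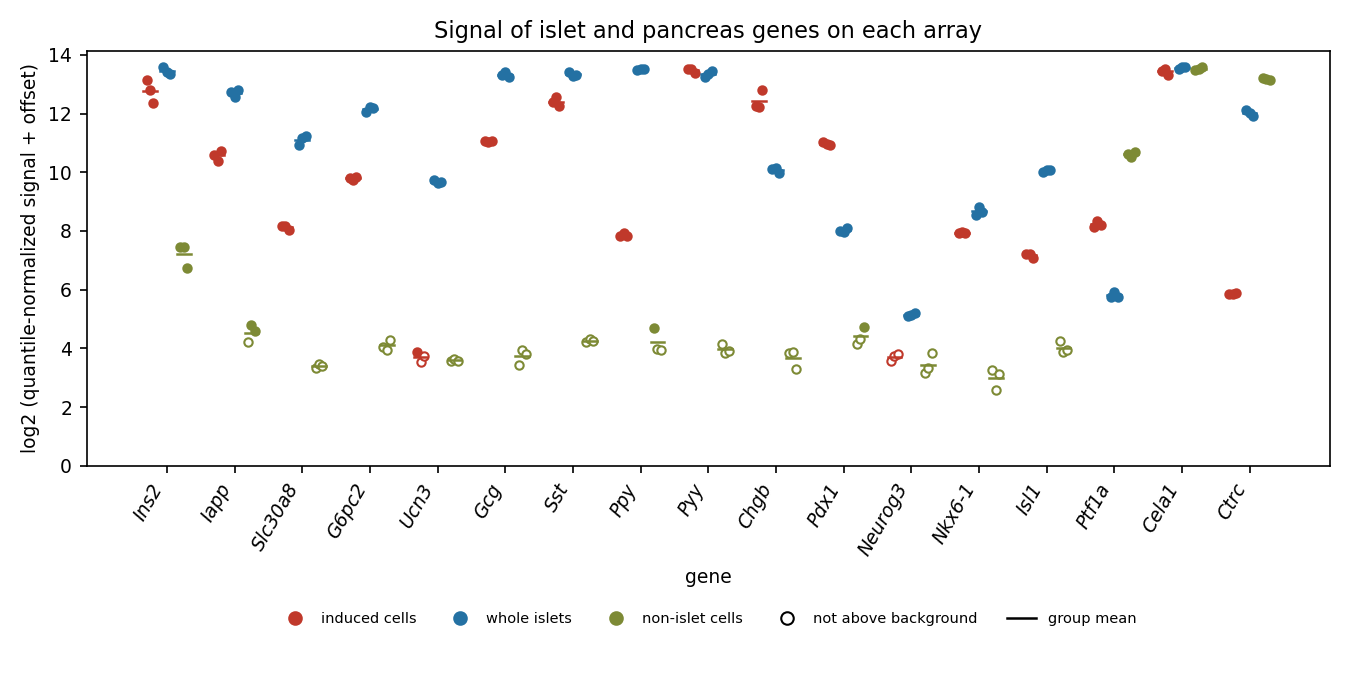
Log2 of the quantile-normalized signal plus the offset for 17 named genes, with 1 dot per array, open where the probe was not above background, and a line at the mean of the 3 arrays of each group (induced, islet, non-islet). The means of Ppy were 221 in induced cells and 11640 in islets before the log, while those of Pyy were 11370 and 10440.

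The acinar list went both ways. Ctrc, a chymotrypsin gene, had a signal of 46.0 ± 0.545 in induced cells and 4133 ± 334 in islets (-6.16, adjusted p = 4.43e-12). Aqp8, a water channel gene, Spink1, a trypsin inhibitor gene, and Amy1, an amylase gene, were higher in induced cells (2.75, 1.64 and 1.44). Of 30 measured acinar genes, 10 were higher and 6 lower, with the same counts adjusted over the list alone. The median was -0.03, the mean 0.05 and the direction of the test up (camera adjusted p = 0.349). The balance turned with the scaling, with 11 higher and 18 lower in the values as deposited and 11 higher and 3 lower with the arrays scaled to a common median. Cpa1 and Cela1, genes of a carboxypeptidase and an elastase, were bright in both groups and not called (-0.04 and -0.13, adjusted p = 0.713 and 0.259) but called lower in the values as deposited (-0.44 and -0.48, adjusted p = 0.00104 and 0.00221, ranges 0.00104 to 0.916 and 0.00221 to 0.595), whereas Amy2a5 was lower (-0.34, adjusted p = 0.036) and Prss2 higher (0.31, adjusted p = 0.0324). Acinar transcription factors were higher for 5 of 7 genes and lower for 1, also adjusted over the list alone (median 1.07, camera adjusted p = 0.0359; adjusted p = 0.321 with an estimated correlation). Ptf1a, needed for acinar identity, Gata4 and Rbpjl were higher by 2.42, 2.02 and 1.53, and Bhlha15 was lower by its brightest probe (-1.55) but not by the dimmest of its 3 kept probes (-0.20, adjusted p = 0.19). Of 14 duct genes 11 were higher and 2 lower, also adjusted over the list alone (median 1.18, camera adjusted p = 8.08e-05). The higher genes included the mucin gene Muc1 (3.62), the keratin gene Krt8 (3.29), the claudin gene Cldn3 (2.28) and Sox9, a duct and progenitor transcription factor (1.88, adjusted p = 1.64e-08). Krt19, another duct keratin, was dim in every group (0.88, adjusted p = 0.00109).

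The largest rises were in Dmbt1, a gene for a secreted protein of mucosal epithelia (8.58, SE 0.079), in Reg3b and Reg3a, secreted lectin genes induced in pancreatitis (7.48 and 7.44), in 1810009J06Rik (6.74) and in Bnip5 (6.11). Injury and regeneration genes were higher for 13 of 19 members and lower for 2, also adjusted over the list alone (median 1.94, camera adjusted p = 6.78e-07). Reg2 rose by 5.29 and Lcn2, an acute-phase gene, by at least 27.6-fold (adjusted p = 9.2e-11). Of 26 interferon response genes 19 were higher and 0 lower (20 and 0 adjusted over the list alone; median 0.88, camera adjusted p = 1.64e-07). Oas2 and Oasl1, of the 2-5A synthetase family, were at least 10.1-fold and 3.96-fold higher, and the regulator Irf1 and the antiviral gene Rsad2 were higher by 2.81 and 2.15. Class I antigen processing had 9 of 10 genes higher and 0 lower (10 and 0 adjusted over the list alone; median 0.76, camera adjusted p = 8.08e-05). H2-T23, B2m, H2-K1 and Nlrc5 were higher by 3.47, 3.35, 2.31 and 0.99. Immediate early and dissociation stress genes moved with these groups: 15 of 19 were higher and 0 lower (15 and 1 adjusted over the list alone; median 1.32, camera adjusted p = 3.28e-07). The higher genes included Atf3 (4.40), Klf6 (3.16), Hspb1 (2.99) and Zfp36 (1.95).

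Markers of vessels, stroma and blood were lower in induced cells. All but 2 of 17 endothelial genes were lower and 0 higher, also adjusted over the list alone (median -2.48, camera adjusted p = 9.8e-11). Esm1 was at least 41.1-fold lower, and Emcn, Flt1 and Plvap were lower at -4.78, -4.71 and -4.35. Stellate and fibroblast genes were lower for 13 of 16 members and higher for 2 (14 and 2 adjusted over the list alone; median -1.04, camera adjusted p = 0.000219). The lower genes included Mgp (-3.26), Dcn (-2.26), Acta2 (-1.87) and Col6a1 (-1.75). The 3 erythrocyte genes measured were lower, also adjusted over the list alone, with Hba-a1 at -5.58, Hbb-b2 at least 14.2-fold lower and Alas2 at -0.81. Macrophage and myeloid genes were lower for 10 of 17 and higher for 3 (11 and 3 adjusted over the list alone; median -0.69) without a call for the list (camera adjusted p = 0.0565). It was called with a common median, at equal noise and without induced array 3 or islet array 2 (adjusted p = 0.0362, 0.0048, 0.0412 and 0.0486, range 0.0048 to 0.155). Laptm5 and Coro1a were lower (-1.90 and -1.29), though of the 2 other kept probes of Coro1a 1 was lower (-0.46, adjusted p = 0.0274) and 1 not called (-0.18, adjusted p = 0.124, range 1.03e-10 to 0.124), Fcgr3 was at least 1.71-fold lower and Cd14 was higher (1.68). Class II antigen presentation had 4 of 6 genes lower and 0 higher, also adjusted over the list alone (median -1.91, camera adjusted p = 0.0123; adjusted p = 0.0611 with an estimated correlation). The lower genes were Cd74 (-2.06), H2-Aa (-1.95), H2-Eb1 (-1.93) and H2-Ab1 (-1.88). Of 4 T and B lymphocyte genes 1 was lower (Cd79a, at least 1.09-fold), and of 4 NK and cytotoxic genes 2 were lower (Ccl5, at least 1.46-fold, and Il2rb, -0.47), with the same counts adjusted over the list alone and too few genes for a list test.

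Endoplasmic reticulum stress genes were lower for 11 of 19 members and higher for 4, also adjusted over the list alone (median -0.75, camera adjusted p = 0.0326; adjusted p = 0.263 with an estimated correlation). The chaperone genes Sdf2l1, Hyou1 and Creld2 and the glutathione-degrading Chac1 were lower at -2.49, -1.73, -1.59 and -1.29. Genes usually kept low in beta cells were higher for 9 of 17 and lower for 3, also adjusted over the list alone (median 0.46, camera adjusted p = 0.0188; adjusted p = 0.0611 with an estimated correlation). Ldha, a lactate dehydrogenase gene, rose by 3.17, Mgst1 by at least 5.18-fold and Zfp36l1 by 1.86, and Igfbp4 was lower (-1.80). Respiratory chain genes were lower for 12 of 28 and higher for 1, also adjusted over the list alone (median -0.26, camera adjusted p = 0.0361; adjusted p = 0.133 with an estimated correlation). Atp5g1, Cox8a and Sdhc were lower (-1.02, -0.82 and -0.80) and Ndufa4 higher (0.86). Ribosomal protein genes were lower for 13 of 24 and higher for 2 (14 and 2 adjusted over the list alone; median -0.39, camera adjusted p = 0.0361; adjusted p = 0.371 with an estimated correlation). Rps16, Rpl38 and Rps29 were lower (-0.86, -0.85 and -0.73) and Rpl22 higher (0.78). The other kept probe of Rpl38 was not called (-0.23, adjusted p = 0.227, range 6.38e-05 to 0.227). Relative to all genes the respiratory chain and ribosomal lists stood at 0.00991 and -0.0476 with the arrays scaled to a common median, and at 0.0688 and 0.00374 with the arrays scaled to equal noise. Proliferation genes were higher for 1 of 11 (Mcm6, 0.86) and lower for 4, also adjusted over the list alone (median -0.15, camera adjusted p = 0.235). Cenpa (-0.66), Mcm5 (-0.56) and Ccne1 (at least 1.14-fold) were lower. Adipocyte genes were higher for 4 of 8 and lower for 2 (5 and 2 adjusted over the list alone; median 0.37, camera adjusted p = 0.208). Lpl was higher by 1.37, Plin1 and Cidea by at least 1.78-fold and 1.44-fold, and Pparg lower. Of 3 Schwann and neural genes Egr2 was higher (2.45) and Sox10 at least 1.09-fold lower, also adjusted over the list alone, with no list test.

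In all, 3134 of 13928 probes were higher and 3641 lower in induced cells than in islets (limma, adjusted p under 0.05). By gene these were 2387 and 2705 of 9937. The share of calls that were higher was 46.3%, against 52.8% with the arrays scaled to a common median, 39.5% in the values as deposited and 61% with the arrays scaled to equal noise. The calls of Nkx6-1 and Nkx2-2 were lost under all 3 of these scalings, and that of Ins2 with a common median and at equal noise (highest adjusted p over the alternatives 0.541, 0.665 and 0.163, lowest 3.77e-06, 0.000432 and 0.00189). The call of Amy2a5 was lost at equal noise, and that of Sst too (adjusted p = 0.0973, range from 8.44e-07). Leaving out 1 array ended the call of Ins2 (without any of induced 2 and 3 or islet 1 to 3, adjusted p up to 0.108), Neurod1 (induced 1 and 3, islet 1 and 2, up to 0.105), Amy2a5 (induced 2 and 3, islet 1 to 3, up to 0.143) and Prss2 (induced 1 and 3, islet 1 to 3, up to 0.136). Over all alternatives their adjusted p ran from 0.00189, 1.36e-05, 0.00129 and 3.99e-05 up to 0.163, 0.105, 0.234 and 0.136. Of the lists, endoplasmic reticulum stress lost its call with a common median, in the values as deposited and at equal noise (adjusted p = 0.103, 0.14 and 0.114, range over the camera alternatives 0.0153 to 0.263), genes usually low in beta cells at equal noise (0.0844, range 0.014 to 0.0844) and acinar transcription factors at offset 50 and at equal noise (0.0664 and 0.0516, range 0.0225 to 0.321). The respiratory chain and ribosomal calls were lost under the same 3 scalings, and with a common median 2 genes were higher and 4 lower in the first list and 2 and 3 in the second. Without induced array 1 or 2, islet array 1 or non-islet array 1 the ribosomal call was lost (adjusted p = 0.0503, 0.0675, 0.0581 and 0.0533, range over the camera alternatives 0.0122 to 0.972), without induced array 2 the respiratory chain call (0.068, range 0.0152 to 0.972) and without islet array 1 that of acinar transcription factors (0.0502). With a common median, calls were also lost for Cd79a (adjusted p over the alternatives 1.59e-06 to 0.353), Ccl5 (4.42e-06 to 0.496, also in the values as deposited), Mcm5 (1.6e-05 to 0.147), Rps16 (0.000107 to 0.138, also at equal noise), Rps29 (0.00514 to 0.686, also at equal noise and without induced array 2), Cidea (1.72e-06 to 0.482) and Sox10 (6.68e-05 to 0.0689), and at equal noise for Cox8a (8.74e-07 to 0.0971).

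The second comparison set the induced cells against the non-islet cells, which the labels give as the tissue outside the islets. Hormone and granule genes separated them most. Pyy, Chgb and Sst were at least 541-fold, 262-fold and 259-fold higher in induced cells, since none of the non-islet arrays was above background (adjusted p = 7.09e-13, 2.07e-11 and 7.68e-13). Cryba2, a crystallin gene, was at least 132-fold higher, and Chga was higher by 8.06 (SE 0.23), with 2 of 3 non-islet arrays above background. Ins2 had a signal of 141 ± 39.7 in non-islet cells and was higher in induced cells by 5.55 (SE 0.22, adjusted p = 1.8e-09). Ctrc was lower at -7.33, followed by Hamp2, a hepcidin gene (-5.49), Vtn, which encodes vitronectin (-5.39), the acinar water channel gene Aqp12 (-5.31) and Sostdc1, which encodes a secreted antagonist of bone morphogenetic proteins (-4.78).

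Beta cell genes were higher for 18 of 23 members and lower for 3 (median 2.94, camera adjusted p = 3.06e-05), and for this comparison the counts of every list were the same adjusted over the list alone. Iapp was higher by 6.04, Pdx1 by 6.57, Slc2a2 by 1.61, and Npy, G6pc2, Abcc8, a subunit gene of the ATP-sensitive potassium channel, Slc30a8 and Nkx6-1 by at least 29.9-fold, 42.4-fold, 33.7-fold, 13.3-fold and 11.7-fold. Pcsk1 was at least 1.10-fold higher. Ucn3 was above background on 1 of 3 induced arrays and no non-islet array and was not called (adjusted p = 0.259), but called at 0.27, 0.24 and 0.28 with a common median, in the values as deposited and at equal noise (adjusted p over the alternatives 0.0232 to 0.677). The other hormone cell list was higher for 9 of 12 genes and lower for 1 (median 3.01, camera adjusted p = 0.000975). Gcg was at least 101-fold, Etv1 at least 39.6-fold and Ppy 3.66 log2 units higher. The other kept probes of Etv1 were higher by at least 2.25-fold and by 0.83 log2 units. Granule genes were higher for 21 of 27 and lower for 3 (median 2.93, camera adjusted p = 4.88e-05). Resp18 (at least 82.5-fold) and Cpe, the carboxypeptidase that trims prohormones (5.66), were higher. Endocrine transcription factors were higher for 12 of 16 and lower for 3 (median 3.17, camera adjusted p = 0.0014; adjusted p = 0.11 with an estimated correlation). Insm1, Rfx6 and Nkx2-2 were higher by at least 35.1-fold, 20.4-fold and 16.5-fold and Neurod1 by 3.19. Neurog3 was not above background in either group, and was called higher in induced cells in the values as deposited (0.54), at equal noise (0.40) and without non-islet array 3 (0.44; adjusted p over the alternatives 0.00254 to 0.412).

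Acinar genes were lower for 18 of 30 members and higher for 0 (median -0.47, camera adjusted p = 7.56e-05), for 29 in the values as deposited (median -2.13) and for 30 with the arrays scaled to a common median (median -2.88). Pnliprp2 and Cuzd1, of a lipase-related protein and a zymogen granule protein, were lower at -2.83 and -2.78, Prss2 at -2.13 and Amy2a5 at -0.39 (adjusted p = 0.0117). Cpa1 was not called at 0.13 (adjusted p = 0.17) and stood at -2.63 with the arrays scaled to a common median, -1.88 in the values as deposited and -0.30 at equal noise, each called, as was 0.13 at offset 50 (adjusted p over the alternatives 3.03e-09 to 0.34). Cela1 was not called at -0.10 (adjusted p = 0.334) but called at -2.84, -2.09 and -0.51 under these 3 scalings (adjusted p over the alternatives 7.42e-09 to 0.709). Acinar transcription factors were lower for 6 of 7 and higher for 1 (median -2.38, camera adjusted p = 0.00295; adjusted p = 0.171 with an estimated correlation). Bhlha15, Nr5a2, Rbpjl and Ptf1a stood at -3.34, -3.18, -3.17 and -2.38. Duct genes were higher for 9 of 14 and lower for 2 (median 1.15, camera adjusted p = 0.0189; adjusted p = 0.139 with an estimated correlation). Krt7 and Krt8 rose by 5.44 and 2.47, Cldn7 and Tspan8 by at least 4.51-fold and 2.05-fold. Sox9 was lower (-0.73) but higher at equal noise (1.72), and not called in the values as deposited (0.23). Krt19 was not called (0.32, adjusted p = 0.1) but called in the values as deposited (0.44), at equal noise (1.06) and without non-islet array 1 (0.52; adjusted p over the alternatives 2.34e-07 to 0.467).

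Interferon response genes were higher for 22 of 26 members and lower for 3 (median 1.70, camera adjusted p = 3.25e-05). Irf1 and Rsad2 were higher by 4.55 and 4.23 and Oas2 and Irf9 by at least 7.02-fold and 6.89-fold. Class I genes were higher for 7 of 10 and lower for 2 (median 1.07) without a call for the list (camera adjusted p = 0.0684). H2-T23 and B2m were higher by 5.15 and 3.65 and Psmb9 by at least 5.54-fold, and Psmb10 was lower (-3.36). Injury genes were higher for 14 of 19 and lower for 4 (median 1.57, camera adjusted p = 0.0061; adjusted p = 0.151 with an estimated correlation). Lcn2 and the chemokine gene Cxcl1 rose by at least 19.1-fold and 21.9-fold, Tnfrsf12a by 3.04 and Reg3a by 2.98. The injury call was lost with the arrays scaled to a common median, in the values as deposited and at equal noise (adjusted p = 0.131, 0.198 and 0.105; range over the camera alternatives 0.00466 to 0.198). Immediate early genes were higher for 18 of 19 and lower for 1 (median 2.43, camera adjusted p = 1.64e-06). Fosb and Atf3 were at least 42.8-fold and 30.8-fold higher, Dusp1 and Ier3 higher by 4.85 and 4.61. Endoplasmic reticulum stress genes were lower for 13 of 19 and higher for 3 (median -0.63, camera adjusted p = 0.0061; adjusted p = 0.171 with an estimated correlation). Sdf2l1 (-3.21), Edem1 and Asns (-2.57) were lower, while Ddit3 was higher (2.63).

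Endothelial genes were lower for 11 of 17 members and higher for 1 (median -0.42, camera adjusted p = 0.00515; adjusted p = 0.139 with an estimated correlation). Emcn, Flt1, Plvap and Pecam1 stood at -2.61, -2.57, -2.15 and -1.33. In the values as deposited 10 endothelial genes were lower and 5 higher (median -0.34), and with a common median 10 and 2 (median -0.57). Stellate and fibroblast genes were lower for 8 of 16 and higher for 2 (median -0.38, camera adjusted p = 0.117), and the list was called in the values as deposited and at equal noise (adjusted p = 0.021 and 0.0115, range 0.0115 to 0.171). Dcn and Gsn were lower (-2.81 and -1.63), Acta2 was at least 1.27-fold higher, and Col6a1 was lower (-1.58) but at 0.24 under equal noise. Myeloid genes were higher for 7 of 17 and lower for 3 (median 0.24, camera adjusted p = 0.377). The higher genes included Cd14 (at least 3.61-fold), Lgals3 (at least 1.71-fold), Fcer1g (at least 1.01-fold) and C1qa (0.72). Class II genes were higher for 3 of 6 and lower for 0 (median 0.91, camera adjusted p = 0.135). The higher genes were H2-DMa (at least 1.33-fold), H2-Ab1 (1.37) and H2-Aa (1.15). Of 4 T and B genes 2 were lower (Ms4a1, -1.61, and Cd3d, at least 1.28-fold), and of 4 NK genes 3 were lower (Il2rb, Klrb1c and Klrk1, at -1.33, -1.01 and -0.96, where Il2rb and Klrk1 turned to 0.10 and 0.01 at equal noise). The 3 erythrocyte genes were lower (Hba-a1, -4.42, Hbb-b2, and Alas2, -1.04). Genes usually low in beta cells were lower for 14 of 17 and higher for 2 (median -0.92, camera adjusted p = 0.000975), and in the values as deposited lower for 9 and higher for 6 (median -0.26). Ndrg2, Smad3 and Yap1 were lower (-2.63, -2.48 and -1.67) and Mgst1 at least 3.58-fold higher. Respiratory chain genes were lower for 23 of 28 and higher for 0 (median -0.85, camera adjusted p = 0.000106), but in the values as deposited lower for 7 and higher for 5 (median -0.15). Sdhb, Ndufb9, Cyc1 and Ndufb5 stood at -1.80, -1.60, -1.45 and -1.27, but at 0.56, 0.82, 0.90 and 1.17 under equal noise, where the direction of the list's test turned up without a call (-0.0556 relative to all genes, adjusted p = 0.282, range over the camera alternatives 3.23e-05 to 0.282). Ribosomal genes were lower for 17 of 24 and higher for 0 (median -0.67, camera adjusted p = 0.00118; adjusted p = 0.171 with an estimated correlation). Rpl38, Rpl32, Rps15 and Rpl10a stood at -1.75, -1.53, -1.40 and -1.36, each above 0 under equal noise. With a common median 21 ribosomal genes were lower and 1 higher (median -1.44), and in the values as deposited 17 and 3 (median -0.73). Proliferation genes were higher for 2 of 11 and lower for 4 (median -0.07, camera adjusted p = 0.581), and in the values as deposited higher for 5 and lower for 1. Mcm5 was higher (0.70), Tpx2 at least 1.21-fold lower, and Tyms and Pcna lower (-1.05 and -0.77) but above 0 under equal noise. Adipocyte genes were higher for 4 of 8 and lower for 2 (median 0.12, camera adjusted p = 0.664). Lpl (1.73), Cidea (1.04) and Plin1 (at least 1.23-fold) were higher and Fabp4 at least 1.68-fold lower. Of 3 Schwann and neural genes Egr2 (at least 6.27-fold) and Mbp (1.06) were higher.

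**Figure D2:**
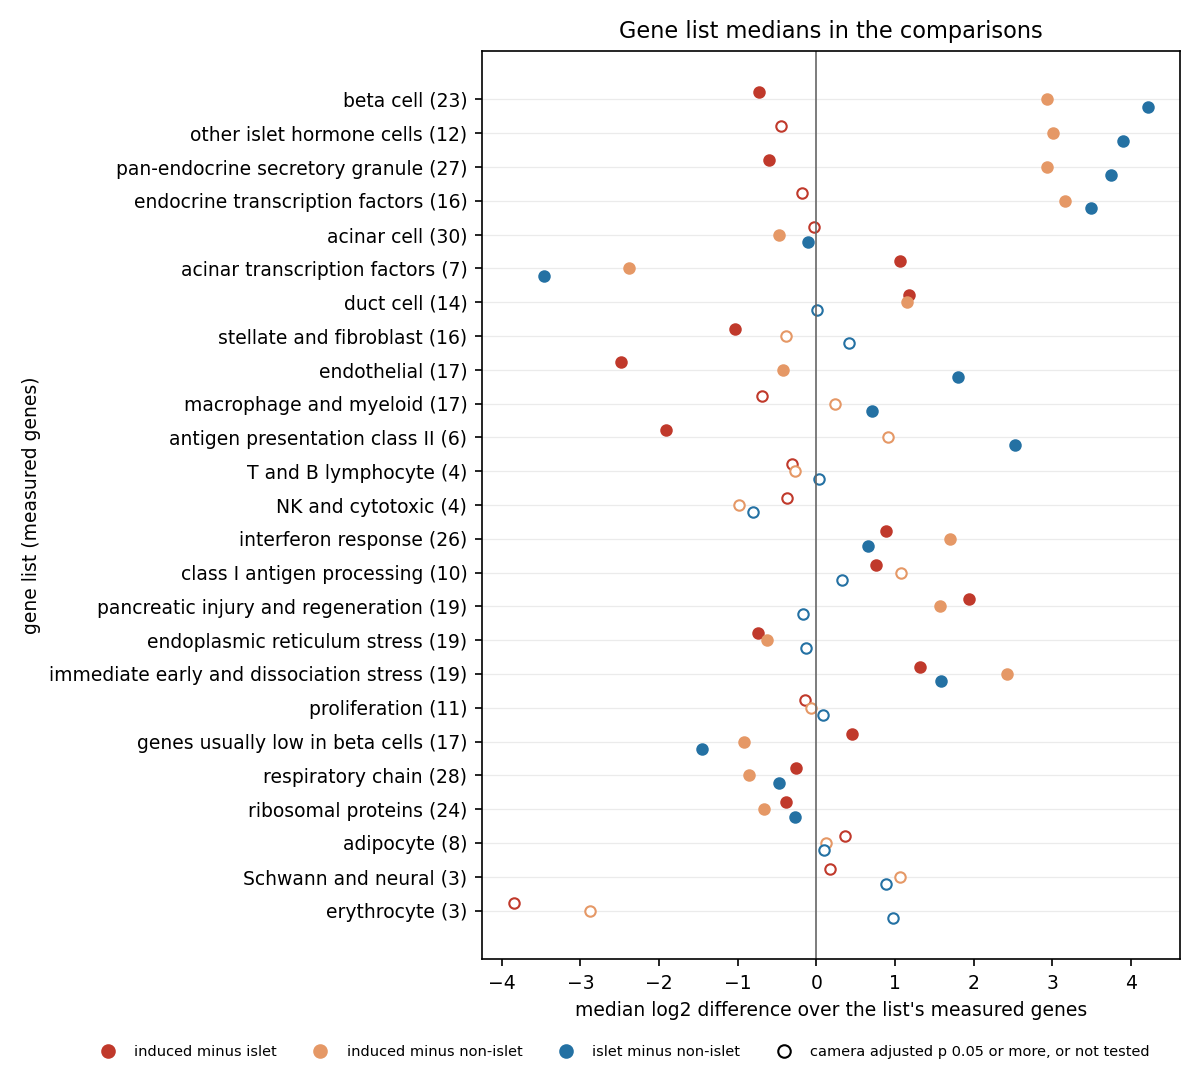
Median log2 difference of 25 gene lists in the 3 comparisons (induced minus islet, induced minus non-islet, islet minus non-islet), with filled symbols where the camera adjusted p was under 0.05 and the number of measured genes in brackets. The endothelial list lay at -2.48 between induced cells and islets and at 1.80 between islets and non-islet cells. Medians of the acinar, respiratory chain and ribosomal lists changed with the scaling of the arrays.

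Between induced and non-islet cells 5517 probes were higher and 5091 lower (limma), or 4042 and 3654 genes. Scaling mattered most in comparisons with the non-islet arrays: the median log2 difference over all probes was 0.05 here and 0.09 between islet and non-islet cells, but 0.13 and 0.13 with the arrays scaled to a common median, 0.50 and 0.62 in the values as deposited, and 1.26 and 1.16 at equal noise, and the printed list medians include these shifts, while the camera tests compare a list with all other genes. Calls were higher in 52% of cases, against 54.9%, 71.5% and 94.6% under those 3 scalings. At equal noise the calls of other hormone cells, endocrine transcription factors and endoplasmic reticulum stress (adjusted p = 0.0698 each, with lowest values over the camera alternatives of 0.000425, 0.00117 and 0.00483 and highest of 0.0698, 0.11 and 0.171), genes usually low in beta cells (0.202, range 0.000714 to 0.202) and ribosomal genes (0.464, range 1.43e-06 to 0.464) were lost. The call of Tpx2 was lost under all 3 scalings, with the 2 groups alone and without induced array 2 or 3 or non-islet array 2 or 3 (adjusted p over the alternatives 0.000102 to 0.369). Calls were lost in the values as deposited for Tyms (2.67e-05 to 0.136), Pcna (3.21e-08 to 0.92) and Ndufb5 (5.93e-08 to 0.0649), at equal noise for Pecam1 (3.67e-07 to 0.386), Ms4a1 (1.2e-08 to 0.329), Cd3d (0.000192 to 0.12), Klrb1c (2.18e-07 to 0.426), Yap1 (1.41e-08 to 0.214) and Alas2 (1.82e-05 to 0.0514), and without induced array 3 for Amy2a5 (3.27e-09 to 0.0503).

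The third comparison set islets against non-islet cells, to find the genes that separate the endocrine from the exocrine pancreas. Hormone genes led again. Gcg, Pyy and Sst were at least 485-fold, 497-fold and 492-fold higher in islets, Ppy was higher by 9.30 (SE 0.17), with 1 of 3 non-islet arrays above background, and Scg2 was at least 278-fold higher (adjusted p = 8.6e-13, 4.09e-13, 4.09e-13, 5.48e-12 and 2.5e-12). Ins2 was higher by 6.23 (SE 0.22) and Iapp by 8.16 (SE 0.15). Lowest in islets were Slc39a5, a zinc transporter gene (-5.41), the kallikrein gene Klk1b8 (-5.38), Tead2, a transcription factor of the Hippo pathway (-5.07), Cabp2 (-4.97) and Itih4 (-4.95). Acinar transcripts were bright on the islet arrays too, with a quantile-normalized signal of 12210 ± 405 for Cpa1 and 10840 ± 109 in non-islet cells. These values do not rank the groups, since the highest deposited value was 8363.5 on the islet and 25197 on the non-islet arrays. In the values as deposited Cpa1 was lower in islets (-1.44).

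Beta cell genes were higher for 20 of 23 members and lower for 1 (median 4.22, camera adjusted p = 2.75e-07), and adjusted over the list alone the counts differed only for interferon response and ribosomal genes. G6pc2, Slc30a8, Gjd2, Ucn3 and Nkx6-1 were higher by at least 218-fold, 104.5-fold, 50.8-fold, 38.9-fold and 19.4-fold, Slc2a2 by 3.70, Pdx1 by 3.63 and Pcsk1 by 0.47. Of 12 genes of other hormone cells 10 were higher and 2 lower (median 3.89, camera adjusted p = 0.000475). Granule genes were higher for 23 of 27 and lower for 3 (median 3.75, camera adjusted p = 3.07e-07). Resp18 and Chgb were higher by at least 347-fold and 51.4-fold and Chga and Scg5 by 8.35 and 6.54. Endocrine transcription factors were higher for 12 of 16 and lower for 3 (median 3.49, camera adjusted p = 0.00138; adjusted p = 0.0773 with an estimated correlation). Isl1, Insm1, Nkx2-2 and Neurog3 were higher by at least 50.5-fold, 37.7-fold, 23.9-fold and 1.68-fold, and Neurod1 by 2.57.

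Acinar genes were lower for 14 of 30 members and higher for 0 (median -0.10, camera adjusted p = 0.000236), and for 30 in the values as deposited (median -1.76) and with the arrays scaled to a common median (median -2.70). Aqp12, Amy1, Serpini2 and Aqp8 were lower at -4.89, -4.20, -4.12 and -3.65, and Prss2 at -2.45. Cpa1, Cela1 and Amy2a5 were not called (0.17, 0.03 and -0.05, adjusted p = 0.077, 0.745 and 0.721). With the arrays scaled to a common median they stood at -2.38, -2.54 and -2.64, in the values as deposited at -1.44, -1.60 and -1.70 and at equal noise at -0.22, -0.38 and -0.48, and all were called (lowest adjusted p over the alternatives 2.68e-08, 6.63e-08 and 2.72e-08, highest 0.188, 0.935 and 0.911). Cpa1 was also called at offset 50 (0.17). Acinar transcription factors were lower for 7 of 7 (median -3.46, camera adjusted p = 0.000236; adjusted p = 0.103 with an estimated correlation). Ptf1a, Rbpjl, Nr5a2 and Gata4 stood at -4.80, -4.70, -3.54 and -3.46. The duct list split, with 5 of 14 higher and 6 lower (median 0.01, mean 0.02, direction of the test down, camera adjusted p = 0.717), and in the values as deposited 8 were higher and 4 lower (median 0.71). Krt7 was higher (5.00), Tspan8 at least 4.39-fold, and Muc1, Sox9 and Krt19 were lower (-4.56, -2.62 and -0.55).

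Endothelial genes were higher for 16 of 17 members and lower for 0 (median 1.80, camera adjusted p = 2.4e-05; adjusted p = 0.0511 with an estimated correlation). The higher genes included Esm1 (at least 28.6-fold), Robo4 (2.63), Icam2 (at least 2.32-fold) and Tek (at least 2.72-fold). Stellate and fibroblast genes were higher for 9 of 16 and lower for 4 (median 0.41, camera adjusted p = 0.351). Mgp and Col3a1 were higher by 2.49 and 1.40 and Acta2 and Thy1 by at least 4.62-fold and 1.54-fold. Myeloid genes were higher for 13 of 17 and lower for 1 (median 0.71, camera adjusted p = 0.0112; adjusted p = 0.0695 with an estimated correlation). Laptm5 was higher by 2.14 and Coro1a, C1qb and C1qc by at least 2.59-fold, 1.49-fold and 1.42-fold. Of the 2 other kept probes of Coro1a 1 was higher (0.45, adjusted p = 0.0206) and 1 was not called (-0.17, adjusted p = 0.111, range for Coro1a 6.16e-15 to 0.111). Class II genes were higher for 5 of 6 and lower for 0 (median 2.53, camera adjusted p = 0.013; adjusted p = 0.0695 with an estimated correlation). H2-Ab1, H2-Aa, Cd74 and H2-Eb1 stood at 3.25, 3.10, 2.73 and 2.33. Of 4 T and B genes 2 were higher (Cd79a, 0.95, and Cd79b, 0.29) and 1 lower (Ms4a1, -1.74), with a median of 0.03 and a mean of -0.18. Of 4 NK genes Ccl5 was at least 1.02-fold higher and Klrk1, Il2rb and Klrb1c were lower (-0.92, -0.86 and -0.74), which stood above 0 at equal noise. The 3 erythrocyte genes had 2 higher, Hba-a1 (1.16) and Hbb-b2 (0.98).

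Interferon response genes were higher for 18 of 26 members and lower for 4 (18 and 5 adjusted over the list alone; median 0.65, camera adjusted p = 0.0167; adjusted p = 0.0666 with an estimated correlation), as for Rsad2, Irf1 (2.08 and 1.73), Psmb9 and Irf9 (at least 3.11-fold and 1.86-fold). This call was lost in the values as deposited and at equal noise (0.258 and -0.254 relative to all genes, adjusted p = 0.203 and 0.763; range over the camera alternatives 0.0147 to 0.763). Class I genes were higher for 4 of 10 and lower for 3 (median 0.33, mean -0.05, direction of the test up, camera adjusted p = 0.831). H2-T23 was higher (1.69) and Psmb10 and Nlrc5 lower (-3.93 and -1.83). Injury genes were higher for 7 of 19 and lower for 9 (median -0.18, camera adjusted p = 0.195), and the list was called lower in the values as deposited and at equal noise (-0.723 and -1.1 relative to all genes, adjusted p = 0.00485 and 3.62e-06, range 3.62e-06 to 0.438). Reg3b, Reg3a, Reg3d and Lgals1 stood at -4.64, -4.46, -4.30 and -3.68. Immediate early genes were higher for 13 of 19 and lower for 3 (median 1.59, camera adjusted p = 0.00609; adjusted p = 0.0534 with an estimated correlation). Dusp1, Fos and Socs3 were higher by 3.53, 3.11 and 3.02 and Fosb by at least 12.4-fold. Endoplasmic reticulum stress genes were higher for 6 of 19 and lower for 8 (median -0.14, camera adjusted p = 0.351), and in the values as deposited higher for 10 and lower for 6 (median 0.34). Edem1, Sel1l and Asns were lower (-2.87, -2.72 and -1.53) and Pdia3 higher (2.06). Genes usually low in beta cells were lower for 14 of 17 and higher for 2 (median -1.46, camera adjusted p = 7.49e-05), and in the values as deposited lower for 11 and higher for 3 (median -0.47). Ldha, Smad3, Ndrg2 and Cxcl12 stood at -4.50, -2.58, -2.42 and -2.25. Respiratory chain genes were lower for 19 of 28 and higher for 2 (median -0.48, camera adjusted p = 0.006; adjusted p = 0.0666 with an estimated correlation). Sdhb, Ndufb9, Uqcrc1 and Cyc1 stood at -1.68, -1.55, -1.14 and -1.10, but all 4 above 0 under equal noise. In the values as deposited 8 were higher and 7 lower (median 0.15). Ribosomal genes were lower for 11 of 24 and higher for 1 (11 and 0 adjusted over the list alone; median -0.27, camera adjusted p = 0.0172; adjusted p = 0.375 with an estimated correlation). Rpl10a, Rpl32, Rpl14 and Rps15 stood at -1.27, -1.09, -1.06 and -0.92, all 4 above 0 under equal noise. With a common median 22 ribosomal genes were lower and 0 higher (median -1.31), and in the values as deposited 14 and 4 (median -0.40). Proliferation genes were higher for 3 of 11 and lower for 3 (median 0.09, -0.03 with a common median, camera adjusted p = 0.923), and in the values as deposited higher for 6 and lower for 0. Mcm5 was at least 1.43-fold higher, and Tyms, Mcm6 and Pcna were lower (-0.95, -0.79 and -0.66) but above 0 under equal noise. Adipocyte genes were higher for 3 of 8 and lower for 2 (median 0.10, mean -0.01, direction of the test up, camera adjusted p = 0.923). Pparg was at least 1.53-fold higher, and Scd1 lower (-1.33) but at 0.79 under equal noise. Schwann and neural genes were higher for 3 of 3, at 0.89 for Mbp, 0.37 for Sox10 and at least 1.15-fold for Egr2.

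Probes higher in islets than in non-islet cells numbered 5646 and lower 4756 (limma), or 4116 and 3455 genes. Calls were higher in 54.3% of cases, against 54.9% with a common median, 77.1% in the values as deposited and 94% at equal noise. In the values as deposited and at equal noise the myeloid and class II calls were lost (adjusted p = 0.0975 and 0.0673, then 0.549 and 0.101, ranges over the camera alternatives 0.00859 to 0.549 and 0.00968 to 0.101), and at equal noise also those of endocrine transcription factors (0.0617, range 0.000867 to 0.0773) and ribosomal genes (0.429, range 1.78e-06 to 0.429). The call of Cd79b was lost at offsets 16 and 50, with a common median, with the 2 groups alone and without induced array 1, any islet array or non-islet array 2 or 3 (adjusted p over the alternatives 0.000282 to 0.186), and that of Sox10 at offset 50, with a replicate block and without induced array 2 or any islet array or non-islet array 1 or 2 (0.000343 to 0.153). Calls were lost with a common median for Col3a1 (3.99e-09 to 0.0594), in the values as deposited for Il2rb (1.67e-05 to 0.587), Tyms (2.94e-05 to 0.918), Mcm6 (1.76e-06 to 0.0985), Scd1 (9.15e-08 to 0.0594) and Klrb1c (1.17e-06 to 0.155, also with the 2 groups alone and without islet array 2 or 3 or non-islet array 1 or 3), and at equal noise for Krt19 (0.00108 to 0.489, also without islet array 1), Asns (5.09e-09 to 0.15) and Cxcl12 (2.15e-10 to 0.178). The other kept probes of Tyms, Mcm6 and Pparg were not called (adjusted p = 0.0654, 0.0518 and 0.244, the last with a range of 6.89e-12 to 0.244).

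The last question was where induced cells stood between non-islet cells (position 0) and islets (position 1) for genes that separate these on the log2 scale by at least 4-fold. For 532 islet-enriched genes the median position was 0.776 ± 0.00721 (SD over the induced arrays, n = 3) and 0.578 on the linear scale. Of them 491 were higher in induced than in non-islet cells, 12 were lower and 29 not called. Against islets 328 fell short, 78 lay beyond and 126 were not called. Independent lists would overlap in 216.4 genes. Simulations in which induced cells did not differ from non-islet cells gave 0, where almost nothing can be called, so that this value says little about the shared non-islet arrays. Part of the excess may come from these arrays, which are too few to split for the overlap. With the genes chosen on 2 replicate numbers and measured in the third, the median position was 0.782, 0.77 and 0.763. For 304 non-islet-enriched genes the median position was 0.829 ± 0.00693, and 0.947 on the linear scale. Of them 282 were lower in induced than in non-islet cells and 10 higher. Against islets 177 fell short, 20 lay beyond and 107 were not called, with 111.8 genes for independent lists and 0 in the simulations. Chosen and measured on separate arrays the median position was 0.846, 0.822 and 0.823. Under equal noise the 2 positions were 1.02 and 0.465.

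**Figure D3:**
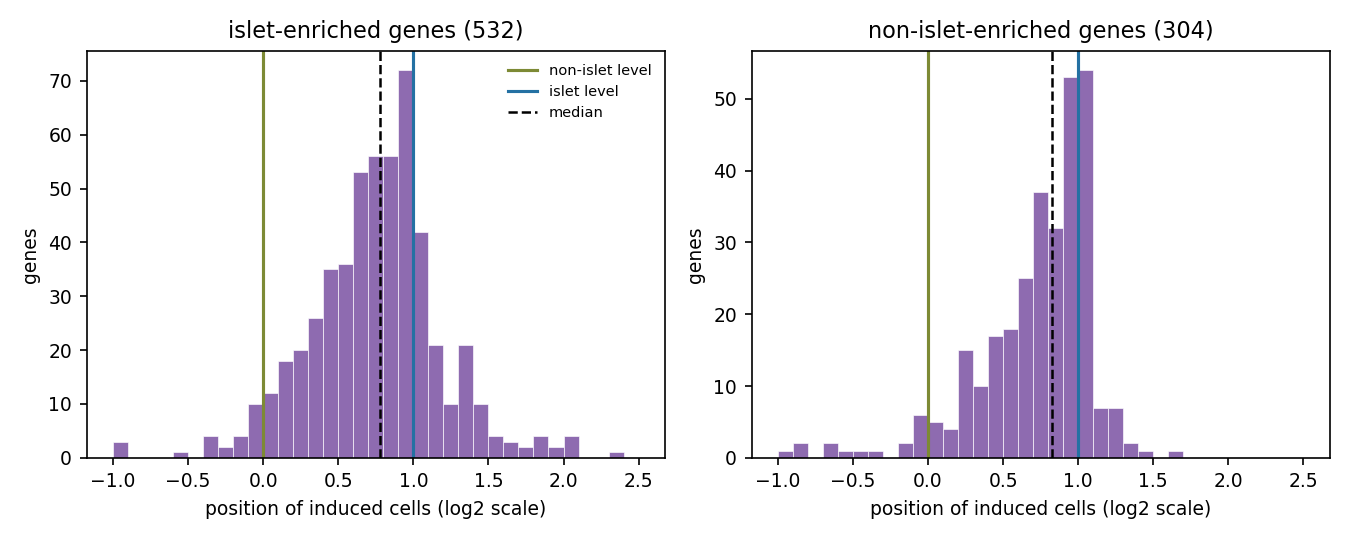
Histograms of the position of induced cells between non-islet cells (0) and islets (1) for 532 islet-enriched and 304 non-islet-enriched genes, with values beyond the ends drawn in the end bins and a dashed line at the median. The medians were 0.776 and 0.829, and 1.02 and 0.465 with the arrays scaled to equal noise.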

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

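The alternatives were chosen before the data were examined, except the scaling of every array to equal noise, which was chosen after seeing the data. Of 1008 camera values of lists under the alternatives 931 kept direction and call, 54 lost the call, 8 gained one, 11 moved and 4 reversed. Of 63 values by fry, which tests a list against no change and not against other genes, 47 kept both, 14 gained a call and 2 moved. Ranges of adjusted p for lists leave fry out. Of 5891 values of named genes 5716 kept both, 103 lost the call, 22 gained one, 7 moved and 43 reversed. Of 63 list results (1 list in 1 comparison) 44 were called, and 19 of these kept call and direction under every alternative run. Of 363 results of named genes 350 were called and 284 of these kept both. An estimated correlation ended 22 list calls. What signal over background limits is the non-islet group, whose noise SD averaged 4.55 against 1.52 in induced cells, so that genes there fall below background at higher signals and folds are lower bounds. The cause of the changes below was not tested, except that a fold limit or a stricter set of probes lowers counts by its construction.

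The replicate numbers showed no consistent pairing of the samples. Correlations of deviations from the group mean between arrays of the same number ran from -0.116 to 0.189, with 2 of 9 over 0.1. With a replicate block in the fit the counts of higher and lower probes were 3067 and 3543 for induced with islet, 5509 and 5073 for induced with non-islet, and 5606 and 4741 for islet with non-islet. The replicate block changed no list call and ended that of Amy2a5 between induced cells and islets (-0.34, adjusted p = 0.0526, range over the alternatives 0.00129 to 0.234) and of Sox10 between islets and non-islet cells (0.37, adjusted p = 0.0623).

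Counts of probes differed by over 1.5 times from the main ones as follows. In the values as deposited 3196 probes were lower in induced than in non-islet cells, and 8769 were higher and 2602 lower in islets than in non-islet cells. With equal noise 5054 were higher in induced cells than in islets, 11132 higher and 637 lower in induced than in non-islet cells, and 11257 higher and 721 lower in islets than in non-islet cells. Among probes detected on all arrays 1743 were higher and 2265 lower in induced cells than in islets, 2035 were higher in induced than in non-islet cells and 2168 in islets than in non-islet cells. With a change of at least 2-fold the counts were 989 and 796, 2499 and 2335, and 2377 and 2157 in the order of the comparisons. Leaving out 1 array moved no count beyond 1.5 times.

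The median position of islet-enriched genes was 0.762 with offset 16, 0.746 with offset 50, 0.882 with median scaling, 0.829 in the values as deposited, 1.02 with equal noise, 0.787 for probes detected on all arrays, 0.763 with the set chosen apart from number 3, and 0.578 on the linear scale. For non-islet-enriched genes it was 0.813, 0.775, 0.82, 0.72, 0.465 and, for probes detected on all arrays, 0.82 in the same order, 0.956 with the 2-fold set, 0.753 with the 8-fold set, 0.846 with the set chosen apart from number 1, and 0.947 on the linear scale. Leaving out 1 array gave 0.768 to 0.79 and 0.825 to 0.855.

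The correlations of induced with islet arrays, and of induced and islet arrays with non-islet arrays, were 0.889, 0.748 and 0.752 with offset 16, 0.895, 0.774 and 0.777 with offset 50, 0.887, 0.708 and 0.717 with median scaling, 0.927, 0.823 and 0.827 with no filter, 0.878, 0.725 and 0.731 with the strict filter, 0.904, 0.765 and 0.767 for probes detected on all arrays, and 0.837, 0.635 and 0.643 by Spearman. The first pair of these was 0.885 and 0.728 in the values as deposited, and 0.88 and 0.727 with equal noise.

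Directions that reversed were mostly in comparisons with non-islet cells. With median scaling Cpa1 stood at -2.63 for induced and -2.38 for islet against non-islet cells, Cela1 at -2.54 for islet and Mt1 at -2.15 for induced against non-islet cells. In the values as deposited Cpa1 stood at -1.88 and -1.44, Cela1 at -1.60, Mt1 at -1.40, Sox9 at 0.23 for induced and Pcna at 0.24 for islet against non-islet cells, the last 2 without a call. With equal noise the direction of the list test turned, without a call, for the respiratory chain and in the first comparison for ribosomal genes: relative to all genes the median of the respiratory chain list was 0.0688 for induced with islet, -0.0556 for induced with non-islet and 0.0665 for islet with non-islet, and that of the ribosomal list 0.00374 for induced with islet. With equal noise, induced against non-islet values were -0.30 for Cpa1, 1.72 for Sox9, 0.24 for Col6a1, 0.10 for Il2rb, 0.0121 for Klrk1, 0.79 for Tyms, 1.01 for Pcna, 0.56 for Sdhb, 0.82 for Ndufb9, 0.90 for Cyc1, 1.17 for Ndufb5, 0.58 for Rpl38, 0.10 for Rpl32, 0.79 for Rps15 and 0.65 for Rpl10a. With equal noise, islet against non-islet values were -0.22 for Cpa1, -0.38 for Cela1, 0.0625 for Klrk1, 0.65 for Il2rb, 0.23 for Klrb1c, 0.78 for Tyms, 0.30 for Mcm6, 1.01 for Pcna, 0.32 for Sdhb, 0.51 for Ndufb9, 0.76 for Uqcrc1, 0.87 for Cyc1, 0.32 for Rpl10a, 0.0249 for Rpl32, 0.27 for Rpl14, 0.85 for Rps15 and 0.79 for Scd1. Of these equal noise values Klrk1 and Rpl32 in both comparisons, Il2rb for induced and Klrb1c for islet against non-islet cells were not called. Of the 2 other kept probes of Coro1a 1 stood at -0.17 and 1 at 0.45 for islet against non-islet cells.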

Other observations

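These genes and the tests below, other than the splits of the arrays, were chosen after the values had been seen. They form no fixed list and had no set test. Signals of the gut hormone genes Gast and Cck in induced cells were 326 ± 47.6 and 206 ± 29.9 (SD, n = 3), at least 23.1-fold and 14.9-fold above islets, where neither was above background. Gip was higher by 3.54, Sct, the secretin gene, by 2.63, and Tph1, the serotonin-synthesis gene, by at least 9.64-fold, while Ghrl and Tac1 were dim, with signals of 4.89 and 5.22, and Tac1 was not called (adjusted p = 0.154). Cdkn1a, a cell cycle inhibitor gene, had a signal of 1382 ± 242 in induced cells and 64.3 ± 8.77 in islets (adjusted p = 1.1e-09), and Gadd45a and Cdkn2b were higher by 2.70 and 1.69. Cdkn2c was lower (-0.94, adjusted p = 2.81e-05), and Cdkn1b and Cdkn2d were not called (0.15 and -0.17, adjusted p = 0.531 and 0.366). The metallothionein genes Mt1, Mt2 and Mt3 were higher than in islets by 1.65, 1.72 and 2.05; against non-islet cells Mt2 was not called (0.00, adjusted p = 0.982) but called at 0.31 with median scaling, 1.02 in the values as deposited and 2.49 at equal noise (adjusted p over the alternatives 8.34e-15 to 0.993), and Mt1 stood at 0.55 but at -2.15 with median scaling and -1.40 in the values as deposited, and was not called at equal noise (0.19). The enzyme genes Psat1, Bcat2 and Gamt were lower in induced than in non-islet cells (-4.15, -4.02 and -3.97) and also in islets than in non-islet cells (-1.97, -3.25 and -4.42).

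Expression of islet genes in the induced fraction could come from resident islet cells carried through the sort on GFP. Carry-over of beta cells would bring all beta genes at 1 share of their islet signal. Over 15 islet-enriched beta genes without Pdx1 the shares differed by a ratio of 9.11 between the 90th and the 10th percentile. The ratio was 47.2 with Pdx1 and 6.61 over 13 genes clear of background and of the top of the range. Ucn3 allowed at most 0.454% of the islet signal, 0.714% after quantile normalization. This bound assumes that its probe reads alike in both mouse lines, which was not tested. The spread of shares argues against carry-over as the only source of these genes as a set. Iapp, Slc2a2 and G6pc2 stood at 23%, 20% and 19.2%, and Slc30a8, Gjd2 and Trpm5 at 12.3%, 12.2% and 11.5%. For these a common share stays possible. Ucn3 and Cltrn lay lower, and the others ran from 35.7% for Papss2 to 1340% for Npy. Islet-level expression in the 22% of insulin-positive cells alone would hold transcription factors near that share; over 9 endocrine factors the lowest median share over arrays and scalings was 78.9% and the highest 113%, with Isl1 at 12.6%, which argues against it for the factors as a set. The beta cell list had a median share of 29.4% (36.5% in the values as deposited, 41.5% with median scaling and 46.8% at equal noise). These medians are over 16 genes with Pdx1 (802%) included, and leaving it out would lower them. Of the 16 genes 8, 6, 6 and 5 lay under 25% in the same order, and 4, 4, 4 and 6 over 75%. Whether beta genes are expressed in the insulin-positive cells alone stays open, though not all at the level of islets given the spread of shares above. Carry-over of alpha, delta and PP cells and induction by the virus, the biological explanation, stay open: the hormone shares differed by a ratio of 57.3, Pyy over Ppy, which decides nothing with Pyy and islet Ppy among the brightest probes, and no cells with a control virus were measured.

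Interferon, class I and injury genes were higher in induced cells than in islets. Injury genes also separated islets from non-islet cells, with 7 of 19 higher in islets and 9 lower, down to -4.64 for Reg3b. Against non-islet cells 14 injury genes were higher in induced cells and 4 lower, and that list call depended on the scaling. How far the injury difference from islets goes with the tissue outside islets was not tested. Immune cells in the sorted fraction, if more abundant than in islets, would raise their own markers. Yet the median difference of 31 members of 4 immune lists was -0.605, with 17 lower and 3 higher and at most -0.544 over the scalings. This argues only against more immune signal than in islets. Islets held it too, with 13 of 17 myeloid and 5 of 6 class II genes above non-islet cells and 1 and 0 below. Against non-islet cells induced cells had 7 myeloid and 3 class II genes higher and 3 and 0 lower. For T and B genes, which Rag-deficient mice can hardly raise, 0 were higher and 2 lower, and for NK genes 0 and 3. Some immune cells thus stay possible. Stress of dissociation and sorting may contribute, since the immediate early list had a median of 1.32, but the sort and the group cannot be told apart. Animals of another sex or strain may also contribute: Eif2s3y, a Y-linked gene, was higher by 4.29, and the labels give Rag-deficient mice for induced cells and Pdx-GFP mice for islets, so that the line goes with the group. The adenovirus itself is a biological explanation that the design cannot separate from these.

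Ctrc was lower in induced cells than in islets. Loss of acinar cells would lower the other acinar genes as well, but their median difference was -0.0109 over 29 genes, from -0.308 to 0.0468 over the scalings, which argues against it as the cause. A variant of the animals' strain at Ctrc or under its probe may be the cause and stays open, since the lowest value of any other acinar gene was -0.779 and the labels give another mouse line for induced cells than for islets, without naming strains. No biological explanation was tested.

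Other splits of the 6 arrays in each comparison are too few for a share under 0.05. They also mix arrays of both groups on each side, so that the group difference enters the residual and few calls are built in. The counts come from fits of the 2 groups alone and so differ from those above. The 10 splits of induced and islet arrays gave 8734 probes for the real split and 0 at most for the others, those of induced and non-islet arrays 10166 and 0, and those of islet and non-islet arrays 9858 and 0, so that 1 split in each reached its real value.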
